A study of Homo sapiens with 22 samples.

How the data were processed

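RNA from 2 human cell lines, Hs578T and TTC642, was prepared as stranded poly(A) libraries from total RNA, per the labels' protocols, and 22 libraries were analysed. The deposited count table holds whole-number read counts per gene symbol, which the authors did not normalise, and its 20114 genes include 1998 with no count in any library. A deposited table of FPKM, scaled by the authors for transcript length and library size, covers 20111 genes. Reads were processed against hg19, per the submitters' processing notes, and the aligner, the counting tool, its use of strand and the annotation are not given in the sources used here. Of the deposited FPKM values, 58 in 8 genes are listed at 0 where the count table holds at least 100 counts, so FPKM served only as an alternative. Genes are named by the symbols of the deposited tables, and no coordinates were used.

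Each column was matched to a sample by the line, hairpin, time and doxycycline state in its name and in the sample title, and no column was left over. The labels put the libraries in 8 groups (2 lines, PRRX1 or non-targeting hairpin, with or without doxycycline), where hairpins 1 and 3 and the time points of 28 and 56 days (4 and 8 weeks) serve as replicates. For the PRRX1 hairpins in Hs578T replicate 1 is hairpin 1 at 28 days, replicate 2 hairpin 3 at 28 days and replicate 3 hairpin 3 at 56 days. In TTC642 replicates 1 and 2 are hairpins 1 and 3 at 28 days, and replicates 3 and 4 the same at 56 days. For the non-targeting hairpin, replicate 1 is 28 days and replicate 2 is 56 days. Libraries with and without doxycycline of the same line, hairpin and time were treated as a pair from 1 culture, since the labels match them on all 3. The pairing was checked across genes: the correlation of the deviations of both members of a pair from their group means ran from −0.431 to 0.605 over the 11 pairs. In 4 of the 7 knockdown pairs another culture correlated better than the own partner (−0.431 against 0.293 and 0.112 against 0.256 for Hs578T hairpin 3 at 28 and 56 days, and 0.0961 against 0.106 and −0.175 against 0.259 for TTC642 hairpin 3 at 28 and hairpin 1 at 56 days). The pairing therefore rests on the labels, and the values do not bear it out for these pairs. No libraries of a group agreed within sampling noise, the smallest chi-square per degree of freedom between them being 23.9.

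The main test was edgeR's quasi-likelihood F test on the counts, with TMM normalisation, filterByExpr on the 8 groups and robust dispersion estimates. Of all genes 14318 were tested. The model had 11 culture blocks and 4 doxycycline effects (line by PRRX1 or non-targeting hairpin) over all 22 libraries, which left 7 residual degrees of freedom. The common biological coefficient of variation was 0.171. The comparisons were with against without doxycycline for the PRRX1 hairpins and for the non-targeting hairpin in each line, the difference between these, their means over both lines, and the difference between the lines. Further fits compared the hairpins, the time points of the doxycycline effect, uninduced cultures (14112 genes), time in culture (14285 genes) and the lines. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05, and "adjusted p" without a tool refers to edgeR for genes and to limma's camera for lists. Changes are log2 values with SE, and CPM values use TMM library sizes. PRRX1 was also tested by exact sign-flip and permutation tests over pairs, two-sided. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

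The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. By that rule PRRX1 is given throughout. For each PRRX1 hairpin comparison the 8 largest rises and 8 largest falls are named among genes with an adjusted p under 0.05, a mean log2 CPM in the line above 1 and the same direction in every pair. Where fewer than 16 pass, those that pass and then the genes of smallest p, up to 10, are given as values. For other comparisons 3 and 3 are named. From each list up to 2 risen and 2 fallen members of smallest p are named, or 2 as values where none pass. Some genes that the rule names are not reported here.

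The 22 lists were mesenchymal and EMT regulators, epithelial junction and identity genes, basal genes, luminal genes, fibrillar collagens and matrix, matrix proteases and inhibitors, myofibroblast and fibroblast markers, mesenchymal developmental transcription factors, TGF-beta responsive genes, YAP/TAZ targets, Wnt components, cell cycle, type I interferon response, inflammatory and NF-kB targets, p53 targets, ATF4 and mitochondrial stress, mitochondrially encoded mRNAs, nuclear oxidative phosphorylation, hypoxia and glycolysis, cholesterol biosynthesis, and markers of haematopoietic and endothelial and of neural and melanocytic cells. Each was tested with limma's camera on log2 CPM (prior count 2, preset correlation 0.01), with an estimated correlation and with fry, adjusted over the lists within a comparison. Members were also counted past the threshold over all genes and adjusted over the list alone.

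The alternatives were DESeq2, other library scalings, no filter or a filter of 1 CPM in 6 libraries, no replicate block, additive culture terms, each line alone, limma on log2 FPKM with pseudocounts of 1 and 0.1, the 28-day libraries alone, hairpin 3 without the hairpin 1 libraries and leaving out each pair. Added after the data were seen were a correction for GC content and transcript length, thinning to the smallest library total of 21318164, leaving out mitochondrially encoded genes, and a fit over all libraries with an effect of its own for each hairpin in each line. GC content and length came from a GENCODE annotation matched by symbol, with values for 10930 of the 10958 genes with a mean log2 CPM above 1. The splits of the libraries were refitted at most 100 times each.

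The steps were tested on simulated counts with 200 genes changed, 100 of them 2-fold and 100 4-fold. For Hs578T knockdown 77 and 95 of these were recovered among 14243 genes, with 5 false calls (2.82% of calls). For TTC642 knockdown 83 and 91 were recovered among 14245 genes, with 14 false calls (7.45%), and for the mean of both lines 91 and 99 among 14230 genes. For the TTC642 difference between PRRX1 and non-targeting hairpins 26 and 82 were recovered among 14230 genes. A simulated shift of the interferon list by 0.5 gave a camera adjusted p of 4.58e-17 with 0 of the other 21 lists called. The simulated genes varied independently and their pair changes carried no GC or length trend. The changed genes were drawn only from those with higher mean counts. These rates therefore do not carry over to lists of correlated genes, to such trends or to genes of low counts. Totals of 21318164 to 68734976 counts make counting error small for genes above a few CPM, so the number of pairs limits the precision of those. Where a group had 0 counts, 3 counts set the floor.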

Results

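Poly(A) RNA was sequenced from 22 libraries of 2 human tumour cell lines that carried doxycycline-inducible short hairpin RNAs against PRRX1, a homeobox transcription factor of mesenchymal cells, or a non-targeting hairpin. Hs578T is a mesenchymal breast cancer line. TTC642 is described as a rhabdoid tumour line in the sample labels, while the series description counts both lines as triple-negative breast cancer, and it is called only TTC642 here. Cells were kept with doxycycline at 3 µg/ml or without it for 28 or 56 days. The series title concerns transcriptional drivers of triple-negative breast cancer, and the comparisons ask which transcripts change when PRRX1 is depleted. Each combination of line, hairpin, time and doxycycline state had 1 library, and Hs578T with hairpin 1 was sampled at 28 days only. The 8 groups therefore held 2 and 2 libraries (non-targeting, without and with doxycycline) and 3 and 3 libraries (PRRX1 hairpins) in Hs578T, and 2, 2, 4 and 4 libraries in TTC642. A pair is a library with and the library without doxycycline of the same line, hairpin and time. The replicates of a group are hairpins and time points, nothing states that they came from separate cultures, and p-values measure only the spread between these samples. Library totals ran from 21318164 to 68734976 counts. Mitochondrially encoded transcripts took 1.18% to 3.71% of the counts in Hs578T and 4.31% to 12.1% in TTC642, where the highest share belonged to the non-targeting culture with doxycycline at 28 days.

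PRRX1 itself was lower with doxycycline in all 7 pairs that carried a PRRX1 hairpin. In Hs578T its level was 233 ± 27.7 CPM without and 89.5 ± 25.9 CPM with doxycycline (mean ± SD, n = 3 each), while the non-targeting cultures held 236 ± 39 and 261 ± 24.7 CPM (n = 2 each). In TTC642 it was 1500 ± 215 CPM without and 509 ± 218 CPM with doxycycline (n = 4 each), against 1670 ± 9.93 and 1460 ± 94.8 CPM with the non-targeting hairpin (n = 2 each). The remaining transcript ranged from 14.3% (TTC642, hairpin 1, 56 days) to 52.1% (Hs578T, hairpin 3, 28 days). With hairpin 1, 23.8%, 32.2% and 14.3% remained in the 3 pairs, and with hairpin 3, 52.1%, 41.9%, 49.5% and 44% remained in the 4 pairs. The non-targeting pairs kept 92.5% and 134% in Hs578T and 83.9% and 91.2% in TTC642. Over the 7 pairs the mean log2 change was −1.56 ± 0.68 (SD), with an exact two-sided sign-flip p of 0.0156, the smallest that 7 pairs can give. Within a line the smallest possible exact p was also reached, 0.25 for 3 pairs and 0.125 for 4 pairs, so neither could pass 0.05. The change exceeded that of the non-targeting pairs by −1.54 (exact permutation p = 0.00303, two-sided, the smallest of 330 assignments, which also exchange pairs between the lines). Within a line this difference was −1.58 in Hs578T (exact permutation p = 0.1, the smallest possible) and −1.47 in TTC642 (exact permutation p = 0.133, where 0.0667 was possible). In the edgeR fit PRRX1 changed by −1.65 ± 0.26 (SE) in TTC642 (adjusted p = 0.0101) and by −1.53 ± 0.20 over both lines (adjusted p = 0.00563). The value in Hs578T, −1.42 ± 0.29, had an unadjusted p of 0.000299 and an adjusted p of 0.102. Leaving out the Hs578T hairpin 1 pair gave an adjusted p of 0.0662 over both lines, leaving out the TTC642 hairpin 1 pair at 28 days gave 0.0602 in TTC642, and leaving out the TTC642 hairpin 1 pair at 56 days gave 0.00114 in Hs578T.

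**Figure D1:**
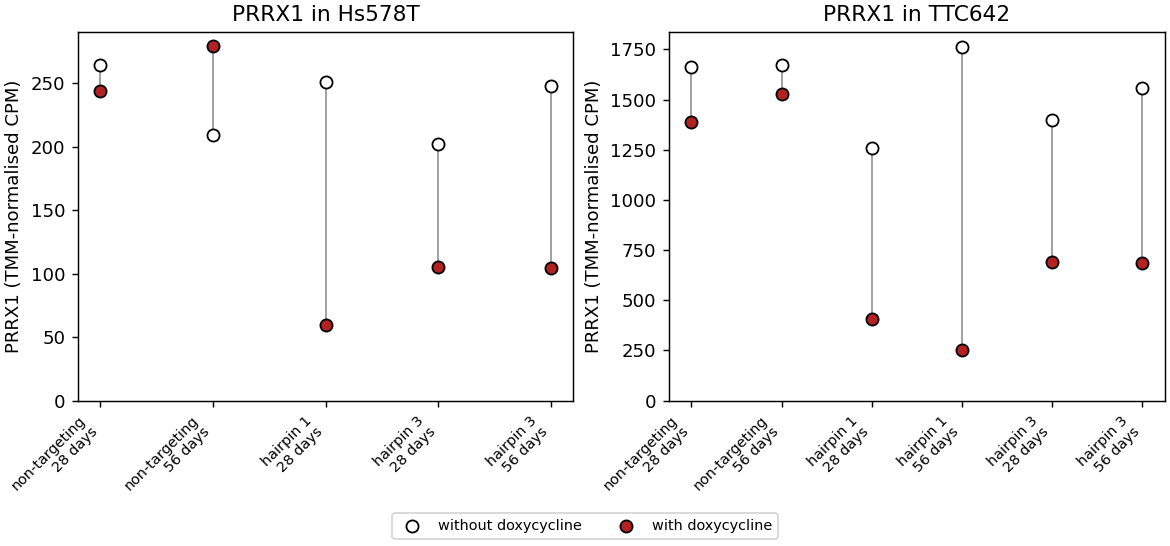
PRRX1 (TMM-normalised CPM, y axis) in each of the 22 libraries by line, hairpin and days (x axis), with open circles for libraries without doxycycline, filled circles with doxycycline and a line joining each pair. The 7 pairs with a PRRX1 hairpin fell to between 14.3% and 52.1% of their partner, and the 4 non-targeting pairs lay between 83.9% and 134%.

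In Hs578T, the genes that fell with PRRX1 knockdown included secreted matrix components and the paralogous homeobox gene PRRX2. MGP, which inhibits matrix calcification, fell from 15.3 ± 4.14 to 3.29 ± 0.93 CPM (log2 −2.21 ± 0.37 SE), PCOLCE, an enhancer of procollagen processing, from 162 ± 39.9 to 61.1 ± 9.83 CPM (−1.39 ± 0.23), and the proteoglycan BGN from 170 ± 52.5 to 73.2 ± 20.3 CPM (−1.20 ± 0.19; mean ± SD, n = 3 each). PRRX2 fell from 25.4 ± 6.72 to 10.4 ± 1.29 CPM (−1.26 ± 0.19). TRAF1, an adaptor of tumour necrosis factor receptors, fell by 1.86 and the succinate receptor SUCNR1 by 1.72 on the log2 scale. IFITM1, an interferon-inducible membrane protein, fell by 1.29, TMEM59L by 1.31, CRIP2 by 0.99, SLC45A1 by 0.96 and MACROD1 by 0.78. Among genes above the expression minimum, LCP1, an actin-bundling protein, was the gene that rose, from 57.3 ± 16 to 107 ± 17.6 CPM (log2 0.92 ± 0.15). These 12 genes had adjusted p-values between 0.0066 and 0.039 and moved the same way in all 3 pairs, while their fitted means over the 2 non-targeting pairs lay between −0.38 and 0.23 except for MGP at −0.96. Single non-targeting pairs ranged more widely, and at 28 days MGP stood at −1.65, TRAF1 at −0.80 and SUCNR1 at −0.78.

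In all, 3 genes rose and 13 fell in Hs578T among 14318 tested, and 2177 genes had an unadjusted p under 0.05. The genes outside the naming rule, chosen after their values were seen, were the netrin receptor UNC5C, which rose from 0.58 ± 0.41 to 33.5 ± 12.9 CPM (n = 3; log2 5.85 ± 0.46, adjusted p = 0.005), the protocadherin PCDH15 (3.01 ± 0.44), the calcium channel gene CACNA1H (−2.85 ± 0.47) and the phospholipase PLA2G4C (−1.76 ± 0.29). CACNA1H also stood at −2.04 and −0.52 in the non-targeting pairs at 28 and 56 days, against −2.54, −3.41 and −1.93 in the knockdown pairs. UNC5C reached 48.4 CPM with hairpin 1 and 26.3 and 25.7 CPM with hairpin 3, while it stood at 0.31 and 0.26 CPM, and at 0.58 and 0.97 CPM, in the non-targeting pairs. Of the 16 genes, 14 moved in the same direction with the non-targeting hairpin, 0 of them by as much as 0.5 times the knockdown change. Across 10958 genes 61.6% had the same sign in both. The knockdown changes of the 16 genes had a median absolute value of 1.35. Their non-targeting changes, counted as negative where opposite, had a median of 0.20. The count depended on single pairs: it was 0 without the hairpin 1 pair, 0 without the hairpin 3 pair at 28 days and 1 without the hairpin 3 pair at 56 days, each of the 12 genes named by the rule losing its call each time. Their changes moved less: over all fits without 1 pair MGP ran from −2.23 to −2.19, BGN from −1.22 to −1.17, SLC45A1 from −0.96 to −0.94 and PCOLCE from −1.45 to −1.33, while SUCNR1 ran from −1.95 to −1.49 and TRAF1 from −2.11 to −1.69. The count was 297 without the TTC642 hairpin 1 pair at 56 days, which shares the estimate of the spread. It was 3 without either Hs578T non-targeting pair, 5 without either of TTC642, and 9 without TTC642 hairpin 1 at 28 days or hairpin 3 at 56 days. It was 248 with DESeq2 (75 up, 173 down), 10 without the culture pairing and 4 up and 8 down with a correction for GC content and length, and of the 12 genes named by the rule 4 and 3 were still called.

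In the lists fixed in advance, few members passed over all genes in Hs578T. None of the 20 tested interferon genes passed over all genes, and 2 were lower when adjusted over the list alone, BST2 at −0.90 and ISG15 at −0.70 (list median −0.03, camera adjusted p = 0.85). Of 16 inflammatory and NF-kB target genes, 14 had negative values and 0 passed over all genes in the edgeR test, against 5 adjusted over the list alone, among them the chemokines IL8 (−1.5) and CXCL3 (−1.35). That list had a median of −0.53 and a camera adjusted p of 0.00651, which became an adjusted p of 0.844 with an estimated correlation. Nuclear oxidative phosphorylation genes had negative values in 21 of 23 members, NDUFA1 at −0.54 and COX4I1 at −0.43 among them. On either adjustment 0 passed (median −0.27, camera adjusted p = 0.011), with an adjusted p of 0.844 with an estimated correlation. Pair medians of this list were −0.17 with hairpin 1, and −0.48 and −0.07 with hairpin 3 at 28 and 56 days. Across all genes the hairpin 1 and hairpin 3 pairs at 28 days followed GC content (Spearman correlations −0.382 and −0.753). They also followed transcript length (0.516 and 0.538). At 56 days these correlations were −0.0229 for GC content and 0.0622 for length. Among 23 matrix genes BGN fell, and adjusted over the list alone THBS1 rose and BGN, COL6A1 (−0.62), COL6A2 (−0.70) and DCN (−0.88) fell (median −0.13, adjusted p = 0.258). PRRX2 was the 1 of 22 mesenchymal developmental transcription factors that fell, on either adjustment (median −0.26, adjusted p = 0.426).

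No member of the other lists passed over all genes in Hs578T in the edgeR test. Adjusted over the list alone, KRT14, a keratin of basal epithelium, fell (−1.76) among 10 basal genes, the inhibitors of differentiation ID1 (−0.74) and ID3 (−0.62) among 16 TGF-beta responsive genes, the proline synthesis enzyme PYCR1 (−0.57) among 20 ATF4 and mitochondrial stress genes and CD68 (−0.47) among 5 haematopoietic and endothelial markers, and the proliferation marker MKI67 rose (0.57) among 23 cell cycle genes. The count adjusted over the list alone was 0 for the remaining lists, of which the members of smallest p are given as values. They were SNAI1 (−1.04) and S100A4 (−0.54) of 16 mesenchymal and EMT regulators, DSP (0.42) and SPINT1 (−0.67) of 9 epithelial genes, MLPH (−0.50) of 10 luminal genes, TIMP1 (−0.75) and ADAMTS1 (−0.58) of 17 matrix proteases and inhibitors, and PDGFRA (−1.25) and TPM2 (−0.52) of 13 myofibroblast and fibroblast markers. FJX1 (−0.68) and CTGF (−0.71) led 15 YAP/TAZ targets, SFRP1 (−0.57) and FZD8 (−0.45) 21 Wnt components, FDXR (−0.40) and SESN1 (0.35) 17 p53 targets, and MT-CO3 (0.48) stood among 13 mitochondrially encoded mRNAs. CA9 (−0.97) and ANGPTL4 (−1.24) led 19 hypoxia and glycolysis genes, MVD (−0.63) and MVK (−0.45) 18 cholesterol biosynthesis genes, and TUBB3 (−0.37) and NES (−1.16) 9 neural and melanocytic markers. Camera adjusted p-values of all these lists lay between 0.258 and 0.937. The YAP/TAZ list had a median of −0.02 with camera's direction up.

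In TTC642, the largest rises with PRRX1 knockdown included matrix genes, a growth factor receptor and an actin-associated gene. The receptor PDGFRA went from 4.61 ± 4.97 to 35.4 ± 35.6 CPM (log2 2.61 ± 0.44 SE), the collagen chain COL5A1 from 3.5 ± 1.59 to 23.5 ± 21.7 CPM (2.24 ± 0.40), TGFBI, a secreted matrix protein, from 31.3 ± 26.8 to 126 ± 87.3 CPM (2.17 ± 0.25), and the actin-associated PALLD from 15.7 ± 9.32 to 87.8 ± 76.7 CPM (2.05 ± 0.38; mean ± SD, n = 4 each). Among the largest falls were CCDC68 (−2.89 ± 0.57), the plasminogen activator PLAT (−1.80 ± 0.35), the chemokine CXCL6 (−1.64 ± 0.28) and PRRX1. For these genes the fitted means over the 2 non-targeting pairs lay between −0.51 and 0.53. In the non-targeting pair at 56 days PLAT stood at −1.81, COL5A1 at 0.98 and TGFBI at −0.73. Other named genes had values of the same direction, though none past the threshold, in the non-targeting pairs. The kinase SGK3 (2.48 against 1.58), SCRG1 (2.02 against 2.14), the efflux transporter ABCC3 (1.98 against 1.57) and CD83 (1.96 against 1.62) rose with the PRRX1 hairpins, and the matrix protein POSTN (−1.94 against −2.59), the potassium channel gene KCNQ5 (−2.35 against −1.74), DIRAS3, a small GTPase (−1.68 against −0.74), and PNMA2 (−1.67 against −0.95) fell. The adjusted p-values of these 16 genes ran from 0.0015 to 0.038, and each moved the same way in all 4 pairs, PDGFRA by 0.48 to 4.41.

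In all, 107 genes rose and 55 fell in TTC642, and 1757 genes had an unadjusted p under 0.05. Of the 162 genes, 130 (80.2%) moved in the same direction with the non-targeting hairpin, 65 of them by at least 0.5 times the knockdown change. Across 10958 genes 68.4% had the same sign in both. The knockdown changes of the 162 genes had a median absolute value of 1.37. Their non-targeting changes, counted as negative where opposite, had a median of 0.51. The count was 34 without the hairpin 1 pair at 28 days, 324 without the hairpin 3 pair at 28 days, 30 without the culture pairing, where 5 of 33 named calls held, 16 with TTC642 fitted alone and 393 with DESeq2. Most of the named calls were lost without the hairpin 1 pair at 28 days, ABCC3 holding in 28 of 28 alternatives, SGK3 and CD83 in 26 and TGFBI in 25.

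**Figure D2:**
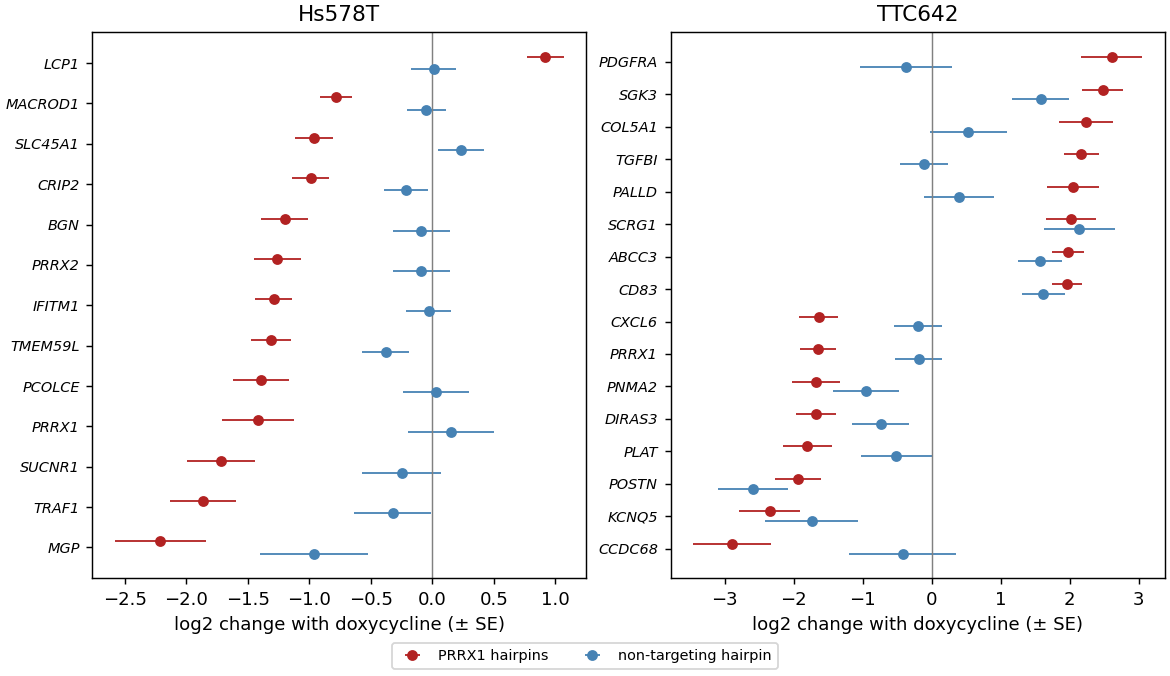
Log2 change with doxycycline (x axis, points, with bars of 1 SE) of the genes named by rule in Hs578T (left) and TTC642 (right), in red for the PRRX1 hairpins and in blue for the non-targeting hairpin. In TTC642 SCRG1 had 2.02 with the PRRX1 hairpins and 2.14 with the non-targeting hairpin, and PDGFRA had 2.61 and −0.37.

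Type I interferon response genes rose together in TTC642. Of the 20 tested members 9 rose, the GTPases MX1 (from 7.63 ± 3.05 to 19.7 ± 6.05 CPM, log2 1.40) and MX2 (1.52), the RNA-sensing synthetases OAS1 (1.76) and OAS2 (1.20), BST2 (1.28), XAF1 (1.29), IFI6 (0.94), IFIT3 (0.94) and IFIT1 (0.75), and none fell. Adjusted over the list alone 15 rose. The median of the list was 0.83, 18 of 20 members were positive, and the camera adjusted p of 4.89e-17 became an adjusted p of 0.0108 with an estimated correlation (fry adjusted p = 0.000213). Pair medians were 1.06 and 1.10 with hairpin 1, 0.44 and 0.53 with hairpin 3, and 0.32 and 0.12 with the non-targeting hairpin. In the non-targeting pairs 0 members passed over all genes and 5 adjusted over the list alone (median 0.22, camera adjusted p = 0.00388, adjusted p = 0.497 with an estimated correlation). The knockdown change minus the non-targeting change had a median of 0.34 and a camera adjusted p of 1.23e-05, with an adjusted p of 0.254 with an estimated correlation. In the 28-day libraries alone the knockdown change had an adjusted p of 0.497 with an estimated correlation, and this p lay between 0.00809 and 0.0396 in the other alternatives.

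Matrix and fibroblast genes gave mixed counts in TTC642. Of 23 matrix genes COL5A1, COL6A2 (0.84) and COL6A1 (0.52) rose and POSTN fell, and adjusted over the list alone 6 rose and 1 fell (median 0.43, camera adjusted p = 0.000822, adjusted p = 0.489 with an estimated correlation). PDGFRA and PDGFRB (0.87) rose among 13 myofibroblast and fibroblast markers, 4 adjusted over the list alone (median 0.75, 2.46e-06, adjusted p = 0.418 with an estimated correlation). The protease ADAMTS1 (1.47) was the 1 of 17 matrix proteases and inhibitors that rose, 3 adjusted over the list alone (median 0.48, 0.00676, adjusted p = 0.489 with an estimated correlation). The hairpin 1 pair at 56 days, whose change followed GC content (Spearman correlation 0.499), had the highest medians of these lists. Matrix genes stood at 1.09 there against 0.20, 0.34 and 0 in the other knockdown pairs. Fibroblast markers stood at 1.80 against 0.52, 0.05 and 0.38, and proteases at 1.86 against 0, 0.12 and 0.18. TGFBI was the 1 of 16 TGF-beta responsive genes, CRIM1 (1.26) the 1 of 15 YAP/TAZ targets and WNT5B (2.60) and DKK3 (1.61) the 2 of 21 Wnt components that rose. Adjusted over the list alone these numbers were 1 up, 2 up, and 2 up with 1 down. The cadherin CDH2 fell (−0.68) among 16 mesenchymal and EMT regulators, against 6 up and 1 down adjusted over the list alone (median 0.12, adjusted p = 0.225).

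No member passed over all genes in the edgeR test for the other lists in TTC642. Adjusted over the list alone the counts were 3 up of 10 basal genes (EGFR 0.94, LAMA3 1.38), 2 up of 10 luminal genes (KRT18 2.46, GATA3 1.61), 1 up of 22 mesenchymal transcription factors (HAND2 1.14), 2 up of 19 hypoxia and glycolysis genes (EGLN3 2.0, ADM 1.89) and 1 down of 16 inflammatory genes (ICAM1 −1.06). They were 0 for 9 epithelial genes (PKP3 0.36, CLDN4 0.55), 23 cell cycle genes (CCNA2 −0.35, MKI67 −0.35; median −0.05), 17 p53 targets (FDXR −0.19, MDM2 −0.21; median −0.01, mean 0.03), 20 ATF4 and mitochondrial stress genes (ATF3 0.53), 13 mitochondrially encoded mRNAs (MT-ND6 0.26, MT-ND3 0.25), 23 oxidative phosphorylation genes (COX5B 0.31, NDUFS1 −0.21), 5 haematopoietic and endothelial markers (CD68 −0.33) and 9 neural and melanocytic markers (MITF −0.35). Camera adjusted p-values under 0.05 were found for hypoxia (0.00676), cholesterol biosynthesis (0.00159), the ATF4 list (0.025), TGF-beta (0.0266) and YAP/TAZ (0.0345), and with an estimated correlation the adjusted p of each lay between 0.489 and 0.624. The Wnt list had a camera adjusted p of 0.0709. The epithelial list had a negative median of −0.03 with camera's direction up (adjusted p = 0.946).

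**Figure D3:**
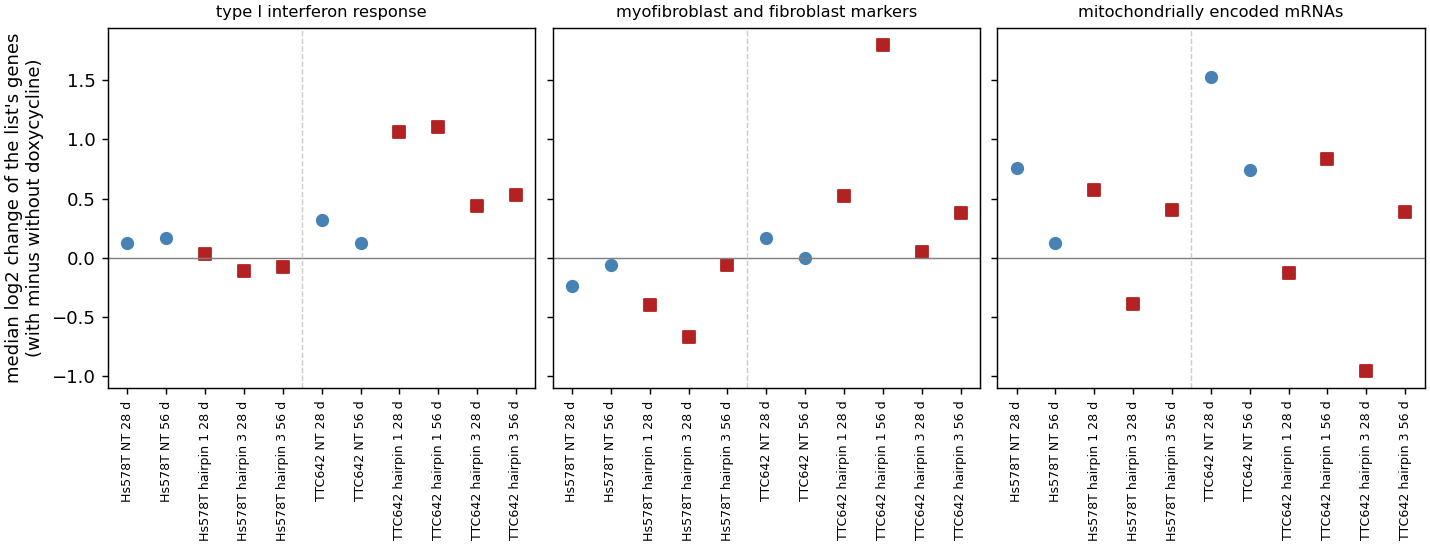
Median log2 change with doxycycline (y axis) of 3 gene lists in each of the 11 pairs (x axis), as red squares for PRRX1 hairpins and blue circles for the non-targeting hairpin, with a dashed line between Hs578T and TTC642. The interferon list stood at 0.44 to 1.10 in the 4 TTC642 knockdown pairs and at 0.12 and 0.32 in the non-targeting pairs.

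The non-targeting cultures measured doxycycline without a PRRX1 hairpin. With 2 pairs per line, 0 genes passed in either line in the edgeR test, with 259 genes at an unadjusted p under 0.05 in Hs578T (DESeq2 0) and 1082 in TTC642 (DESeq2 10). In TTC642 the adhesion gene ALCAM had a value of −1.53 (adjusted p = 0.22), TOX −3.25 (0.22) and the chaperone CLU −1.0 (0.46). In Hs578T the smallest p-values belonged to ICAM5 (1.04), FAM13B (−0.58) and the apolipoprotein gene APOC1 (−1.27), each with an adjusted p of 1. Mitochondrially encoded mRNAs had a median of 1.18 in TTC642, with 0 members past over all genes and 10 of 13 adjusted over the list alone (camera adjusted p = 6.9e-10, adjusted p = 0.497 with an estimated correlation). Their share of all counts went from 4.68% to 12.1% at 28 days and from 4.31% to 6.96% at 56 days in these cultures. In Hs578T the same list had a median of 0.49 (0.0146) and hypoxia genes one of 0.25 (7.64e-05), with adjusted p-values of 0.901 and 0.792 with an estimated correlation.

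The change with a PRRX1 hairpin minus that with the non-targeting hairpin was tested in each line. In Hs578T the smallest adjusted p-values were those of FAM13B (1.35, 0.35), UNC5C (5.45, 0.36), ICAM5 (−2.21, 0.36) and IFITM1 (−1.26, 0.43). In TTC642 they were those of the collagen-crosslinking enzyme LOX (2.15 ± 0.35 SE, 0.46), ALCAM (1.60, 0.6), TGFBI (2.28, 0.6) and the Wnt-associated receptor LGR5 (2.98, 0.6). PRRX1 itself had values of −1.57 ± 0.45 and −1.46 ± 0.43, and −1.51 ± 0.31 over both lines (adjusted p = 0.88). In the edgeR test 0 genes passed in Hs578T, in TTC642 or over both, with 600, 503 and 772 genes at an unadjusted p under 0.05, and DESeq2 called 7, 6 and 4. In the TTC642 simulation 26 of 100 genes changed 2-fold and 82 of 100 changed 4-fold were recovered, so changes near 2-fold would mostly be missed. Its genes varied independently and had no GC or length trend, so these rates do not carry over to the libraries. Here LOX, TGFBI and LGR5 did not pass with fitted changes of 4.45-fold, 4.86-fold and 7.87-fold. The lack of calls therefore does not exclude changes of 4-fold or more. In a fit chosen after the data were seen, each hairpin of TTC642 was set against the non-targeting hairpin. With hairpin 1, 35 genes had a higher and 9 a lower change, and with hairpin 3 0 genes passed. The hairpin 1 calls included DMD (5.67, adjusted p = 0.00076), TIMP3 (4.41, 0.02) and PRRX1 (−2.03, 0.042).

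Averaged over both lines, the named genes that rose included interferon-inducible ones. GBP1 and GBP3, interferon-inducible guanylate-binding proteins, rose by 1.39 and 1.10 on the log2 scale, SAMD9 and SAMD9L by 1.30 and 1.43, DDX60L by 0.93, the interleukin 1 receptor chain IL1RAP by 0.90, SGK3 by 1.38 and PLEKHG1 by 0.86. These are means of both line effects and need not be shared, single pairs running from 0.168 to 3.37 for GBP1 and from 0.034 to 2.78 for GBP3. Beyond the non-targeting change, GBP1 stood at 0.36 in Hs578T and 1.28 in TTC642, GBP3 at 0.05 and 1.35, and SGK3 at −0.05 and 0.90. Of these risen genes only SAMD9L stood higher in Hs578T by that measure (0.66 and 0.29). Levels differed between the lines: SAMD9 went from 80.4 ± 12 to 109 ± 13.4 CPM in Hs578T (n = 3 each) and from 0.70 ± 0.10 to 3.35 ± 1.75 CPM in TTC642 (n = 4 each). The MAP kinase phosphatase DUSP4 fell by 1.01, CLU by 0.84, PLAT by 1.33, the Wnt deacylase NOTUM by 0.95, PRRX2 by 0.85, the protease HTRA3 by 0.79 and CACNG7 by 0.68. The fitted means of these genes over the 2 TTC642 non-targeting pairs had the same direction except for PLEKHG1 and CACNG7. They were 1.97 for SAMD9L, 1.58 for SGK3, 1.20 for GBP1, 0.70 for GBP3, 0.33 for SAMD9 and 0.23 for DDX60L, and −1.10 for DUSP4 and NOTUM, −1.0 for CLU, −0.83 for HTRA3 and −0.51 for PLAT. Over the 2 Hs578T non-targeting pairs these means lay between −0.16 and 0.33, with single pairs as far as −0.39 for SAMD9 and 0.51 for SGK3. In all 22 genes rose and 18 fell, and 1263 had an unadjusted p under 0.05. The count was 5 without the Hs578T hairpin 1 pair, 6 without the Hs578T hairpin 3 pair at 28 days, 96 without the TTC642 hairpin 1 pair at 56 days, 8 without the culture pairing and 26 up and 12 down with the GC and length correction, where 3 and 13 of 19 named calls held. GBP, SAMD9, DDX60 and IFITM genes belong to families with similar sequences, and overlapping or antisense genes share reads where strand is ignored; neither the counting nor its use of strand was stated, so these values are uncertain. Over both lines the interferon list had 1 riser, IFIT3 (0.69), against 10 adjusted over the list alone (camera adjusted p = 2.62e-10, adjusted p = 0.0471 with an estimated correlation). Its pair medians were 0.03, −0.11 and −0.08 in the Hs578T knockdown pairs and 1.06, 0.44, 1.10 and 0.53 in those of TTC642, so the rise lay in TTC642.

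No gene passed in the same direction in both lines, where independent calls would share 0.0224 risen and 0.0499 fallen genes, and PCOLCE passed in opposite directions. The overlap was 5 genes with DESeq2 and 8 without the TTC642 hairpin 1 pair at 56 days. Across 10958 genes, which are not independent replicates, the knockdown changes of the lines had a Spearman correlation of −0.40 with 33% of genes of the same sign, against 0.29 for the non-targeting changes. It was −0.26 with the GC and length correction. With the hairpins given separate effects it was −0.40 for hairpin 1 (32.6% of the same sign) and −0.08 for hairpin 3 (47.6%). Between single knockdown pairs of the lines, Pearson's correlation was −0.373 and −0.487 for the TTC642 hairpin 1 pair at 56 days against the Hs578T pairs at 28 days, 0.00976 for the hairpin 1 pairs at 28 days, and between −0.228 and 0.195 for the others. The change of the TTC642 hairpin 1 pair at 56 days followed GC content with a Spearman correlation of 0.499. The Spearman correlation of the changes was 0.63 between the hairpins in Hs578T and 0.20 in TTC642, 1 family of 8 such correlations. Between knockdown and non-targeting changes it was 0.27 in Hs578T and 0.48 in TTC642. Within Hs578T, Pearson's correlation was 0.63 between the hairpin 1 and hairpin 3 pairs at 28 days. Against the hairpin 3 pair at 56 days it was 0.179 for hairpin 1 and 0.0925 for hairpin 3 at 28 days. Both 28-day pairs followed GC content, with Spearman correlations of −0.382 and −0.753, against −0.0229 in the 56-day pair.

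The knockdown change differed between the lines for 62 genes, PCOLCE and PDGFRA among them. PCOLCE fell in Hs578T and went from 117 ± 25.8 to 224 ± 55.6 CPM in TTC642 (n = 4 each; difference 2.31 ± 0.30 SE, adjusted p = 0.0087). PDGFRA had 261 ± 108 and 106 ± 19.9 CPM in Hs578T (n = 3 each) against its rise in TTC642 (difference 3.86 ± 0.60). IGFBP3, a binding protein of insulin-like growth factors, had 377 ± 82.1 and 156 ± 53.2 CPM in Hs578T and 0.45 ± 0.53 and 8.39 ± 11.5 CPM in TTC642 (4.97 ± 0.75). Taken for single TTC642 pairs against the mean of the Hs578T pairs, the difference ran from 1.72 to 7.84 for IGFBP3 and from 1.72 to 5.66 for PDGFRA. TGFBI (2.31), TRAF1 (2.26), CACNA1H (2.60), ABCC3 (2.39) and VSNL1 (2.37) had higher changes in TTC642, and STK17B (−1.55), STAMBPL1 (−1.42), ABLIM3 (−1.41), FAM13B (−1.14), SORT1 (−1.13) and the DNA repair gene BRCA1 (−0.85) lower ones. Some of these also parted the lines with the non-targeting hairpin, at 28 and 56 days: ABCC3 stood at 1.61 and 1.52 in TTC642 against −0.03 and 0.47 in Hs578T, ABLIM3 at −1.28 and −1.61 against −0.28 and −0.20, SORT1 at −0.73 and −0.94 against −0.17 and 0.21, BRCA1 at −0.48 and −0.44 against −0.07 and −0.02, STAMBPL1 at −0.27 and −0.53 against 0.28 and −0.05, and CACNA1H at −0.43 and −0.23 against −2.04 and −0.52. VSNL1 parted them the other way, at −1.60 and −1.28 against −0.15 and 0.29. In all 55 genes had a higher and 7 a lower change in TTC642 (2915 at an unadjusted p under 0.05). The interferon list differed by a median of 1.07, with 3 members past over all genes (BST2, IFI6, MX1) and 11 adjusted over the list alone (camera adjusted p = 8.39e-07, adjusted p = 0.142 with an estimated correlation). Matrix genes (median 0.76) had 2 higher members, 8 higher and 1 lower adjusted over the list alone (0.00831, adjusted p = 0.592 with an estimated correlation). The count was 3 without the Hs578T hairpin 1 pair, which ended the call of PCOLCE, 257 without the TTC642 hairpin 3 pair at 28 days, 2 without the culture pairing and 692 with DESeq2 (447 higher, 245 lower).

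The hairpins differed for 7 genes at matched line and time, all of which are named here, those beyond 3 in each direction after their values were seen. PRRX1 stood higher with hairpin 3 (1.17 ± 0.20 SE, adjusted p = 0.0461), as did KLHL14 (3.81), SCEL (3.44) and CCDC68 (2.89), and the heart and limb transcription factor HAND2 (−1.72 ± 0.20, 0.0043), the immediate early gene FOSB (−1.40) and the collagen gene COL28A1 (−3.34) stood lower. Among 1788 genes at an unadjusted p under 0.05, the count was 0 without the TTC642 hairpin 3 cultures at 56 days and 171 without the Hs578T hairpin 1 cultures, where the rise against fall was 77 to 94. Mitochondrially encoded mRNAs were lower with hairpin 3 in 12 members adjusted over the list alone and 0 over all genes (median −0.84, 6.7e-09, adjusted p = 0.74 with an estimated correlation).

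Each hairpin was also given its own effect in each line, in a fit over all libraries chosen after the data were seen. In TTC642 with hairpin 1, 352 genes rose and 215 fell, led by the muscle structural gene DMD (5.31 ± 0.37 SE), the growth factor PDGFB (4.76) and the protease inhibitor TIMP3 (4.29) upwards and the lipase LIPG (−5.77), RAB27B (−4.92) and CCDC68 (−4.43) downwards, and PRRX1 changed by −2.22 (adjusted p = 0.000583). With hairpin 3 in TTC642 0 genes passed in the edgeR test (451 at an unadjusted p under 0.05, DESeq2 41), and VEGFC, a lymphatic growth factor, had a value of −2.90 (adjusted p = 0.12). With the hairpin 1 libraries left out of the fit, and so out of the estimate of the spread, hairpin 3 called 54 genes in TTC642 and 31 in Hs578T. The hairpins of TTC642 differed for 38 genes, 11 higher and 27 lower with hairpin 3. Hairpin 1 in Hs578T had a single pair, whose spread was taken to be that of the other groups, so its values have no replicate check. UNC5C had a value of 6.94 and FOSB of 2.28 there, with calls that rest on that borrowed spread, and UNC5C passed with hairpin 3 in 2 pairs (5.33), these genes being named after their values were seen. FOSB also stood at 1.30 and 1.09 in the Hs578T non-targeting pairs. Between the hairpins of Hs578T 0 genes differed in the edgeR test (121 at an unadjusted p under 0.05, DESeq2 1).

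The doxycycline effect with PRRX1 hairpins differed between 56 and 28 days for 966 genes. COTL1, an actin-binding protein (1.32), CAMK2N2, an inhibitor of calmodulin-dependent kinase (1.42), and the AP-1 component FOSL1 (1.30) had higher effects at 56 days, and TMPRSS15 (−1.99), NCAM2 (−1.67) and ATP8A1 (−1.64) lower ones. Of these, 486 genes were higher and 480 lower (3845 at an unadjusted p under 0.05), and PRRX1 had a value of −0.54 (adjusted p = 0.0964). Cell cycle genes gave 7 higher members and 13 adjusted over the list alone (camera adjusted p = 1.04e-05, adjusted p = 0.867 with an estimated correlation), and mitochondrially encoded mRNAs 9 and 12 (median 1.0, 2.12e-07, adjusted p = 0.867 with an estimated correlation). The count was 61 higher and 20 lower with the GC and length correction, 0 without the Hs578T hairpin 3 cultures at 56 days and 3075 without the TTC642 hairpin 3 cultures at 28 days. All 6 named calls ended in the first 2 of these. The non-targeting pairs were fitted without a time difference of their own, so a time difference of doxycycline itself was not subtracted.

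Among libraries kept without doxycycline, cultures with PRRX1 hairpins were compared with non-targeting cultures. Leak of the hairpins and differences between the transduced cultures cannot be told apart in this comparison. In TTC642 MARCKS, an actin-regulating kinase substrate, stood at 5.36 ± 1.83 CPM (n = 4) against 59.1 ± 13.6 CPM (n = 2; log2 −3.46 ± 0.22 SE, adjusted p = 1.2e-05), and the lipid receptor S1PR3 at 4.16 ± 1.13 against 23 ± 7.14 CPM (−2.48 ± 0.23). The laminin LAMB1 was also lower (−1.07), and STK17B (1.5), the kinesin KIF1A (1.23), VGF (1.10), FZD4 (0.97) and ABCC2 (0.84) were the 5 higher genes, of which FZD4 and ABCC2 were named after their values were seen. In all 5 genes were higher and 21 lower in TTC642. The calls of MARCKS and S1PR3 held in 17 of 17 alternatives, and the count was 9 without the non-targeting culture at 28 days and 77 without the hairpin 3 culture at 56 days. In Hs578T 0 genes differed in the edgeR test (137 at an unadjusted p under 0.05, DESeq2 0), and PRRX1 had values of −0.03 in Hs578T and −0.17 in TTC642.

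Between 28 and 56 days in culture, the immediate early gene FOSB fell in both lines, by 2.26 in Hs578T and by 3.42 in TTC642 on the log2 scale. The immediate early transcription factors EGR1 and EGR2 fell by 2.28 and 2.07 in Hs578T. SMCR8 (0.98), FMN1 (0.98) and the synaptic scaffold SHANK3 (0.93) rose in Hs578T. In TTC642 the complement gene CFB (2.16), the stress transcription factor DDIT3 (1.69) and NOTUM (1.51) rose, and TMPRSS15 (−3.34) and MYOC (−3.01) fell. In all 7 genes rose and 32 fell in Hs578T, and 251 rose and 430 fell in TTC642. This comparison took the libraries with and without doxycycline of a culture as separate pairs over time. Its p-values thus treat libraries of the same culture as independent. Time in culture cannot be told apart from the day of harvest or from any processing shared by the libraries of a time point. Of 23 cell cycle genes 12 fell in TTC642, 20 adjusted over the list alone (median −0.44, camera adjusted p = 2.07e-11, adjusted p = 0.267 with an estimated correlation). Among matrix genes COL1A1 (−1.61), COL1A2 (−1.64) and SPARC (−0.88) fell there, as did PDGFRA (−2.68) and TGFBI (−2.51). With the GC and length correction the TTC642 split was 825 up and 924 down, and the Hs578T count was 6 without the untreated non-targeting cultures.

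The lines themselves differed without doxycycline in most tested genes, 5429 higher in TTC642 and 5904 lower of 14112. PRRX1 stood at 1550 ± 189 CPM in TTC642 (n = 6) and 235 ± 27.7 CPM in Hs578T (n = 5; log2 2.75 ± 0.13 SE, adjusted p = 1.67e-10). The retinaldehyde dehydrogenase ALDH1A1 (5290 ± 1410 CPM) and the glucagon gene GCG (2370 ± 430 CPM) were abundant in TTC642 and had 2 and 2 counts over the 5 Hs578T libraries, where 3 counts in the smallest correspond to 0.1 CPM. EDIL3 (424 ± 80 CPM), APCDD1L (420 ± 32.7 CPM) and the Wnt receptor FZD6 (316 ± 34.7 CPM) were abundant in Hs578T and had 1, 1 and 0 counts over the 6 TTC642 libraries, where 3 counts in the smallest correspond to 0.13 CPM. These floors cover counting error only. Among 23 matrix genes 19 were lower and 4 higher in TTC642, and 2 of 13 myofibroblast markers were higher and 10 lower.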

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

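The tests of explanations and the counts of other splits in this part were chosen only after the results they bear on were seen, while the differences between lines, hairpins and times were planned.

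Single libraries stood apart from the rest of their group in 2 of 98 tests on groups of 4 libraries, where chance gives about 1 in 20. HDAC9, a histone deacetylase, was at 0.2 CPM in the TTC642 hairpin 3 library with doxycycline at 28 days, against 0.53 to 0.63 CPM in the other 3, and POSTN was at 27.5 CPM in the TTC642 hairpin 3 library without doxycycline at 28 days, against 67.6 to 74.6 CPM. The gaps to the nearest library were 0.837 and 0.901 of the range, above Dixon's 95% critical value.

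The interferon response list changed differently in the lines, by a median of 1.07 in log2 (fry adjusted p = 0.00221, camera adjusted p = 0.142 with an estimated correlation). The list passed with each hairpin given its own effect in TTC642, the larger adjusted p with an estimated correlation being 0.0186, and 20 of 20 members were positive with hairpin 3. The rise was thus not confined to 1 hairpin. That test did not subtract the non-targeting change, whose pair medians were 0.32 and 0.12, against 0.44 and 0.53 with hairpin 3 and 1.06 and 1.10 with hairpin 1. It therefore cannot tell whether hairpin 1 alone adds to an effect of doxycycline or of any hairpin. The GC content and length of its genes is argued against as the whole cause, since the adjusted p with an estimated correlation was 0.0125 after the correction, within a range of 0.00809 to 0.497 over the alternatives. Doxycycline, or the expression of any hairpin, cannot be told apart from PRRX1 knockdown: the difference from the non-targeting pairs had an adjusted p of 0.254 with an estimated correlation (fry unadjusted p = 0.0078, adjusted p = 0.172), and only 2 non-targeting pairs were sequenced. A response to the loss of PRRX1 in TTC642 stays open as an untested hypothesis.

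Genes whose knockdown change differed between TTC642 and Hs578T, by a test of the difference itself, were higher in TTC642 for IGFBP3 (4.97), PDGFRA (3.86), CACNA1H (2.60), ABCC3 (2.39), VSNL1 (2.37), PCOLCE (2.31), TGFBI (2.31) and TRAF1 (2.26), and lower for STK17B (−1.55), STAMBPL1 (−1.42), ABLIM3 (−1.41), FAM13B (−1.14), SORT1 (−1.13) and BRCA1 (−0.85). Doxycycline, or the expression of any hairpin, stays open as the cause for some of them, since ABCC3 stood at 1.61 and 1.52 in the TTC642 non-targeting pairs against −0.03 and 0.47 in those of Hs578T, ABLIM3 at −1.28 and −1.61 against −0.28 and −0.20, SORT1 at −0.73 and −0.94 against −0.17 and 0.21, and CACNA1H at −0.43 and −0.23 against −2.04 and −0.52. Of the 62 genes, 39 were called again in the same direction with the GC and length correction, 55 with all libraries thinned to 1 depth and 57 without the TTC642 hairpin 1 pair at 56 days, which argues against each as the whole cause. A GC or length trend may still account for the rest. As many genes were called in 5 of 89 splits of the same libraries, the highest other calling 1626, so chance is not excluded by that count. Of the 4 others, 3 part only 3 of the 7 pairs. Within each line these keep the true doxycycline states of the pairs they part or reverse them all. Reversing 1 line as a whole turns the difference into a mean of the line effects. These splits thus hold real effects and say little of chance, and the highest of the 61 fits that do neither called 112. Of 9 splits that part all 7 pairs, the highest other called 12, and a difference in biology between the lines stays open as untested.

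Between 56 and 28 days the doxycycline effect with PRRX1 hairpins differed, by a test of the difference, for CAMK2N2 (1.42), COTL1 (1.32), FOSL1 (1.3), TMPRSS15 (−1.99), NCAM2 (−1.67) and ATP8A1 (−1.64), and for 966 genes in all. After the GC and length correction 61 of the 966 were called again, so most calls did not hold, which a GC or length trend of the libraries could give. A lost call alone does not show that the change itself went away, so that trend stays open. At equal depth 855 were called again, which argues against depth. The correction moved CAMK2N2 from 1.42 ± 0.33 to 0.82 ± 0.31 (SE) and TMPRSS15 from −1.99 ± 0.35 to −1.58 ± 0.38, but COTL1 only from 1.32 ± 0.31 to 1.39 ± 0.29, where the adjusted p alone went from 0.034 to 0.0662. Across genes the change of a pair followed GC content with a Spearman correlation of −0.753 in the Hs578T hairpin 3 pair at 28 days and 0.499 in the TTC642 hairpin 1 pair at 56 days. As many genes were called in 3 of 33 splits, or 2 of 29 once splits that give the same fit are counted once, the highest other calling 2638, so chance is not excluded and time itself stays open. A time difference of doxycycline without a PRRX1 hairpin was not fitted and stays open too. The day of harvest, and any processing shared by the libraries of a time point, cannot be told apart from time.

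Between the hairpins PRRX1 (1.17), HAND2 (−1.72) and FOSB (−1.40) differed, by a test of the difference. As many genes as the 7 called were found in 3 of 33 splits, with 444 in the highest other, so chance is not excluded.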

How the results depend on the processing

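The corrections for GC content and length, the fits that combine them with another choice, and the fits of single hairpins were chosen after the data were seen, and the other alternatives were planned. The planned fit of hairpin 3 alone leaves out the hairpin 1 libraries, while the fits of single hairpins give each hairpin its own effect over all libraries and share 1 estimate of the spread. Changes to counts under fewer libraries or another tool come with fewer samples or another estimate of the spread, and beyond that the cause was not tested. Over all refits of named genes, 3325 kept their side of the threshold, 881 lost and 73 gained a call, and none reversed a called direction. Of the refits of lists, 1070 kept their side, 111 lost and 26 gained a call, and 3 reversed. Of the refitted counts, 253 stayed within 1.5 times and 142 did not.

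For knockdown in Hs578T (16 genes) the count was 248 with DESeq2, 47 with additive culture terms, 428 with the line alone, 165 and 44 with limma on log2(FPKM + 1) and log2(FPKM + 0.1), 2064 in the 28-day libraries, 31 with hairpin 3 alone and 130 with the GC correction in the line alone. For TTC642 (162 genes) it was 393 with DESeq2, 16 with the line alone, 82 and 91 with FPKM, 386 at 28 days, 54 with hairpin 3 alone and 16 with the GC correction in the line alone. Over both lines (40 genes) it was 151 with DESeq2, 23 with log2(FPKM + 0.1), 980 at 28 days and 16 with hairpin 3 alone. The difference between the lines (62 genes) gave 692 with DESeq2, 100 without a filter, 166 with additive terms, 157 and 94 with FPKM, 395 at 28 days and 13 with hairpin 3 alone.

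Without the replicate block, which ignores the culture pairs, the counts were 10 in Hs578T, 30 in TTC642, 8 over both lines and 2 for the difference between lines, and with the GC correction as well they were 58 in TTC642, 4 over both and 1 for the difference. Apart from the genes shared by the lines, given below, the pairing changed no other count by over 1.5 times.

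With the non-targeting hairpin (0 genes) Hs578T had 7 genes at 28 days and 1 in the fit with hairpin 3, and TTC642 had 10 with DESeq2, 63 at 28 days and 4 in the fit with hairpin 3. The difference from the non-targeting hairpin (0 genes) gave in Hs578T 7 with DESeq2, 11 with the line alone, 9 and 1 with FPKM, 55 at 28 days and 1 with hairpin 3, in TTC642 6 with DESeq2 and 103 at 28 days, and over both lines 4 with DESeq2, 1 with each FPKM pseudocount and 770 at 28 days. Genes shared by the lines (0) numbered 5 with DESeq2, 1 with additive terms, 2 with each line alone, 52 at 28 days, 1 with hairpin 3 alone, and 2 with the GC correction in each line alone or without the block.

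The hairpin difference (7 genes) gave 39 with DESeq2, 54 without a filter and 3 with the GC correction. The time difference (966) gave 1499 with DESeq2 and 81 with the GC correction. Uninduced TTC642 cultures (26) gave 98 with DESeq2, 46 without and 11 with a stricter filter. Time in culture gave 208 with DESeq2 and 63 with the GC correction in Hs578T (39), and 1203 and 1749 in TTC642 (681). In the fits of single hairpins, Hs578T hairpin 1 (2) gave 7 with DESeq2, Hs578T hairpin 3 (1) gave 33 with DESeq2, 5 without a filter and 2 with the GC correction, and their difference (0) gave 1 with DESeq2 and 1 without a filter. TTC642 hairpin 1 (567) gave 1017 with the GC correction, TTC642 hairpin 3 (0) gave 41 with DESeq2, 8 without a filter and 2 with the correction, and their difference (38) gave 165, 93 and 98. TTC642 hairpin 1 against the non-targeting hairpin (44) gave 201, 103 and 104.

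PRRX1 in Hs578T (−1.42, adjusted p = 0.102) passed with DESeq2 (−1.40, 0.000531), additive terms (−1.42, 0.0289), the line alone (−1.40, 7.6e-06), at 28 days (−1.50, 6.9e-13), with hairpin 3 (−1.08, 0.013) and with the GC correction without the block (−1.52, 0.0425) or in the line alone (−1.56, 0.00296). In TTC642 (−1.65) it missed the threshold with the line alone (−1.65, 0.072) and with the GC correction there (−1.60, 0.0511). The ATF4 list in TTC642 reversed with hairpin 3 alone (camera adjusted p = 0.904 against 0.025), and the mitochondrially encoded list reversed at 28 days (0.000335 against 0.878) and with hairpin 3 alone (0.016).

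Leaving out 1 pair or culture at a time gave these ranges. Knockdown counts ran from 0 to 297 in Hs578T, from 34 to 324 in TTC642, from 5 to 96 over both lines and from 3 to 257 for the difference between lines. In Hs578T the count was 3 without either non-targeting pair of that line, 5 without either non-targeting pair of TTC642, 9 without TTC642 hairpin 1 at 28 days or hairpin 3 at 56 days, 0 without Hs578T hairpin 1 or hairpin 3 at 28 days, 1 without hairpin 3 at 56 days, 297 without TTC642 hairpin 1 at 56 days and within 1.5 times without TTC642 hairpin 3 at 28 days. Over both lines it was 18 without either Hs578T non-targeting pair, 5, 6 and 23 without Hs578T hairpin 1, hairpin 3 at 28 days and hairpin 3 at 56 days, and 9, 96 and 26 without TTC642 hairpin 1 at 28 days, hairpin 1 at 56 days and hairpin 3 at 56 days. For the difference between lines it was 23 and 24 without the Hs578T non-targeting pairs at 28 and 56 days, 32 without either of TTC642, 3, 12 and 17 without those 3 Hs578T knockdown pairs, and 21, 257, 129 and 28 without TTC642 hairpin 1 and hairpin 3 at 28 days and hairpin 1 and hairpin 3 at 56 days. Non-targeting counts were 0 throughout in Hs578T and ran from 0 to 3 in TTC642, highest without TTC642 hairpin 1 at 56 days. Differences from the non-targeting hairpin stayed at 0 in each line and over both, and shared genes ran from 0 to 8. The hairpin difference ran from 0 to 171: it was 3 without any of the Hs578T non-targeting cultures or hairpin 3 at 56 days, 37 without either TTC642 non-targeting culture, 22 and 2 without TTC642 hairpin 1 at 28 and 56 days, 0 without TTC642 hairpin 3 at 56 days and 171 without Hs578T hairpin 1. The time difference ran from 0 to 3075: it was 126, 2 and 0 without Hs578T hairpin 1, hairpin 3 at 28 days and hairpin 3 at 56 days, 641 without the Hs578T non-targeting culture at 56 days, 25 and 5 without TTC642 hairpin 1 at 28 and 56 days, and 3075 and 2425 without TTC642 hairpin 3 at 28 and 56 days. Uninduced cultures ran from 9 to 77 in TTC642 (15 and 14 without Hs578T hairpin 1 and hairpin 3 at 28 days, 9 without the TTC642 non-targeting culture at 28 days, 47 and 77 without TTC642 hairpin 1 and hairpin 3 at 56 days) and stayed at 0 in Hs578T. Time in culture ran from 6 without the untreated non-targeting cultures to 66 without TTC642 hairpin 1 with doxycycline in Hs578T, with 17 without the treated non-targeting, 14 and 9 without the untreated and treated hairpin 3 cultures of Hs578T, and 23 and 25 without the untreated non-targeting and hairpin 3 cultures of TTC642. In TTC642 it ran from 163 without its untreated non-targeting cultures to 969 without hairpin 1 with doxycycline, with 325 without the treated non-targeting and 270 without the untreated hairpin 1 cultures. The line difference ran from 10482 to 11349. PRRX1 ran from −1.66 to −1.10 in Hs578T, from −1.86 to −1.28 in TTC642 and from −1.66 to −1.35 over both lines. Where 1 pair was left in a group, its spread was taken to be that of the other groups.

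Library scaling by DESeq2's size factors or by total counts gave 17 and 17 genes in Hs578T and 163 and 165 in TTC642. At equal depth 12 of the 16 and 134 of the 162 genes were called again.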

Other observations

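The fits of single hairpins were chosen after the data were seen, and the splits were counted after the results they bear on. The comparison of hairpin 1 with hairpin 3 in TTC642 was written down before its result was seen.

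With hairpin 1 in TTC642, some members of several lists rose and others fell. COL1A1 (3.78), COL5A1 (3.27), COL12A1 (2.95), COL6A2, COL6A3 (1.31) and LOXL2 (1.17) rose among 23 matrix genes. POSTN fell (−2.39), and the list had 9 up and 2 down adjusted over the list alone. In the main fit POSTN also stood at −2.59 over the TTC642 non-targeting pairs, where COL5A1 stood at 0.53. The cadherin CDH11 (3.42) and the EMT transcription factors TWIST1 (1.37), TWIST2 (1.81) and ZEB1 (1.31) rose among 16 regulators, and TCF4 fell (−1.71), with 6 up and 2 down adjusted over the list alone. HAND2 (2.04), MSX1 (2.89), RUNX2 (2.08), FOXD1 (1.5) and TBX15 (0.86) were the 5 of 22 developmental transcription factors that rose, against 5 up and 1 down adjusted over the list alone. Of 15 YAP/TAZ targets 5 rose, with CYR61 at 2.43 and AMOTL2 at 1.63, and NT5E fell (−1.34). PDGFRA (3.48), TPM1 (2.09), MYL9 (1.24) and PDGFRB (1.09) rose among 13 fibroblast markers, 8 adjusted over the list alone. Camera gave adjusted p-values of 2.5e-06 for fibroblast markers, 0.00153 for matrix genes and 0.0151 for YAP/TAZ targets, which became 0.447, 0.46 and 0.46 as adjusted p with an estimated correlation. For the EMT regulators it was 0.23 and for the developmental transcription factors 0.0782, so that none of these lists passed with an estimated correlation. In the hairpin 1 pairs at 28 and 56 days fibroblast markers had medians of 0.52 and 1.80, and matrix genes of 0.20 and 1.09. The change of the 56-day pair followed GC content (Spearman correlation 0.499).

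From 28 to 56 days some p53 targets, inflammatory genes and cell cycle genes were among those that fell in TTC642. CDKN1A (−0.63), FAS (−0.50) and SESN1 (−0.47) fell among 17 p53 targets, all with negative values, 4 adjusted over the list alone (camera adjusted p = 0.000579, adjusted p = 0.175 with an estimated correlation). Members of the cell cycle list, which did not pass with an estimated correlation, fell as well, among them MCM7 (−0.71), MCM4 (−0.69) and MKI67 (−0.57). ICAM1 (−2.24) and PTGS2 (−1.53) fell among 16 inflammatory genes, 2 adjusted over the list alone. In Hs578T the chemokine CXCL2 fell (−1.64) in the same list, 8 adjusted over the list alone, with a median of −0.73 (2.71e-05, adjusted p = 0.788 with an estimated correlation). Without doxycycline 16 of 18 cholesterol biosynthesis genes were lower in TTC642, and of 17 p53 targets 13 were higher and 1 lower. Neither list passed with an estimated correlation (camera adjusted p = 0.202 for each). Of all 14112 genes tested there, 5429 were higher and 5904 lower in TTC642, so many members of any list differ. Of 5 haematopoietic and endothelial markers 5 were lower in TTC642.

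Of the 567 genes called with hairpin 1 in TTC642, 76.4% had the same direction with hairpin 3 and 67.9% with the non-targeting hairpin. With PRRX1 hairpins in Hs578T it was 40%. Across 10958 genes 56.4% had the same sign with both hairpins in TTC642, and that share was not counted for hairpin 1 against the non-targeting hairpin. A change shared by both PRRX1 hairpins could be part of this response, but the share lies only a little above that of the non-targeting pairs. Counted as negative where opposite to hairpin 1, the changes had medians of 0.267 with hairpin 3 and 0.218 with the non-targeting hairpin. With hairpin 1 the median absolute change was 1.68, in genes called by that same change. These data do not decide whether the hairpins share a change.

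UNC5C, singled out after its values were seen, passed in 25 of 27 alternatives in Hs578T, with changes from 2.07 to 6.74 and adjusted p-values from 2.1e-69 to 0.11. It missed the threshold without the hairpin 1 pair (0.068) and without the hairpin 3 pair at 28 days (0.11).

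Other splits of the same libraries were counted for the remaining comparisons. For knockdown in Hs578T the real split called 16 genes and the highest other 0, and the 10 splits are too few for a share under 0.05, so that 1 of 10 is the lowest possible. For knockdown in TTC642 as many genes were called in 3 of 32 splits. The other 2, with 733 genes each, are the same fit, which keeps the true doxycycline states of both hairpin 1 pairs and leaves the hairpin 3 pairs out of the contrast, so they hold the real effect and do not bear on chance. The splits give 20 different fits, too few for a share under 0.05, and the 13 that do not keep the true states called at most 1 gene. Over both lines 4 of 89 splits called as many genes as the real 40, or 4 of 80 once splits that give the same fit are counted once, so chance is not excluded by that count. The highest other called 1002. Of the 3 others, 2 keep the true states of the pairs they part within each line or reverse all of those in a line. Of 9 splits that part all pairs the highest other called 12. For the difference from the non-targeting hairpin over both lines the real split called 0 genes, so 100 of 100 splits had to call as many. The highest called 937, and this count says nothing about chance. Chance was excluded for the lines (1 of 92 splits, 11333 genes against 8305). For time in culture in TTC642 2 of 98 splits called as many genes, 681 against 944 in the highest other, which keeps the true times of the pairs it parts. The highest of 6 that part all pairs called 0. These splits took the libraries with and without doxycycline of a culture as separate, so chance is not excluded by that count. For time in culture in Hs578T the real split alone called as many genes (1 of 32, 39 against 2), but these splits give only 20 different fits, too few for a share under 0.05.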
